A study of Homo sapiens with 246 samples.

How the data were processed

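HEK293T cells were seeded at 30000 cells per well of 96-well plates in medium with serum and transfected 24 h later with FUGENE HD (3 µL per µg of plasmid), per the labels' protocols. RNA was extracted with Trizol 48 h after transfection. Unstranded poly(A) libraries were sequenced as paired reads of 150 bases on a NovaSeq X Plus. TF doses of 1 µg lay in columns 2 and 7 of a plate and doses of 0.05 µg in columns 6 and 11, with the 2 GFP wells in column 12, so dose and column cannot be separated within a TF. The accessibility data that the labels mention were not analysed here.

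The deposited values used are estimated counts per transcript, made by the authors with kallisto 0.46.2 after trimming with cutadapt 3.5, per the submitters' processing notes, which also name the build hg38. The annotation release is not given in the sources used here. The deposited TPM values and effective lengths came from the same tool, and effective lengths entered only the transcript length offsets. Each of the 246 libraries had its own table of 188756 targets. Of these, 169797 were matched to genes by GENCODE release 29 (GRCh38), 15521 by a table of gene names, and 3 are added sequences whose identifiers differ by 1 digit from a transcript of KLF1, XBP1 or FOXO1 and which rose in that TF's wells. The other 3435 targets had no match, held 0.58 to 13.75% of the counts of a library (median 0.76%), and stayed out of library sizes and tests. Estimated counts were summed to 35620 gene symbols and rounded to whole numbers. Reads from a gene and an overlapping or antisense partner cannot be told apart in unstranded libraries, and near-identical genes share reads.

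Library totals were 10222286 to 32484386 counts (median 18233780). Libraries fall in 113 groups of TF and dose or GFP, with groups and replicate numbers from the labels. Whether replicate wells are separate cultures is not stated, so p-values measure only the spread between wells, which may be technical. Where replicates correlated at under 0.95 (lowest 0.611), a library was called apart, in a pair the one less like the plate median (8 libraries in all).

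Tests used edgeR 4.0.16 in R 4.3.3 with limma 3.58.1: TMM scaling, filterByExpr (minimum count 10, total 15), and the quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, in 1 fit per plate with a mean per group, so that all groups of a plate share the estimate of the spread. Each dose was compared with the GFP wells of the same plate. The dose trend is the slope over µg of TF plasmid in the TF wells alone, called at an adjusted p under 0.05 and at least 1 log2 unit per µg. The transfected TF was left out of counts of changed genes. A group at 0 counts was set to a floor of 3 counts over the group for a lower bound of a fold, and genes with 1 to 3 counts in the GFP wells are given as levels. Such bounds cover counting error only.

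The 31 gene lists, the lists paired with each TF and the rule for named genes were fixed before the data were examined. Unpaired lists that lost their call with an estimated correlation are described only in part. Lists were tested with camera (preset correlation 0.01) over a family of 682 tests, where a member rose or fell at an adjusted p under 0.05 over all genes, at any fold. Of these tests 176 passed, 28 of them with an estimated correlation, and of 45 tests of paired lists 15 passed, 4 of them with an estimated correlation. For the B cell list of BACH2 and FOXP1, the FOXO list of FOXP1 and the pluripotency list of OCT4 and SOX2, the list median and the direction of the test differ in sign, and none of these passed. The rule for named genes took the TF gene, the 8 largest rises and 4 largest falls among called protein-coding genes with at least 1 CPM in the higher group that moved the same way in every replicate, up to 6 members with the smallest p of each paired or passing list, the 5 largest in each direction of a direct contrast, and the 10 genes shared by most TFs of a plate. Fewer are named in the text.

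Permutation tests used 100000 resamples, or exact enumeration within plates, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. Data were simulated (FOXP1, plate 1, 16741 genes, 200 changed by 1.5, 2 or 3 log2 units). Of these 97%, 100% and 100% were called at 1 µg, with 8 unchanged genes. The dose trend held 74.6%, 98.5% and 100%, with 2 unchanged genes. A relative response of 0.6 was found as 0.651. Real wells may differ. Of 163 replicate pairs 0 were identical, and all differed by more than sampling noise (chi-square over degrees of freedom of 2.27 or more). Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, transcript length offsets, the replicate number as a block, a fit of only the TF and GFP wells, 6 pooled GFP libraries, a slope over the logarithm of the dose, other gene selections, and each replicate left out in turn. Fits without the libraries that stood apart and with offsets for the GC content of genes were added after seeing the data.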

Results

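RNA sequencing profiles were collected from HEK293T cells, a line derived from human embryonic kidney that carries the SV40 large T antigen, after transfection with plasmids for 22 transcription factors (TFs). Each well received 1 µg of plasmid, made up of TF plasmid (1, 0.75, 0.5, 0.25 or 0.05 µg) and plasmid for green fluorescent protein (GFP), and RNA was taken 48 h later. The libraries came from 3 plates. Plate 1 held SP4, ELF1, FOXP1, GATA1, BACH2, FOXO1, FOXP3 and IRF4. Plate 2 held IKZF2, LEF1, NR4A1, PRDM1, XBP1, ALX4, TCF3 and MXD1, and plate 3 held KLF1, KLF4, OCT4, SOX2, MYC and SPI1. Each dose had 2 wells, or 4 wells for KLF1 and SPI1, and each plate had 2 wells with GFP plasmid alone. A library held 10222286 to 32484386 estimated counts, with a median of 18233780. The series asks how gene expression responds to the amount of each TF. Levels are CPM (counts over TMM-scaled library size, not shares of reads) in TF and GFP wells of a plate, as mean ± SD. Folds compare these groups. A gene was called changed at 1 µg when its adjusted p was under 0.05 and its change at least 2-fold. TF and plate are confounded for comparisons between plates.

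The transcript of every transfected TF was far above its level in the GFP wells at 1 µg (adjusted p from edgeR's quasi-likelihood test under 0.05 for all 22). KLF4 reached 325000 ± 23100 CPM (SD, n = 2), BACH2 283000 ± 3780 CPM, PRDM1 151000 ± 32300 CPM and SPI1 116000 ± 16300 CPM (SD, n = 4), against 12.8, 14.1, 0.134 and 0.217 CPM in the GFP wells. LEF1 (102000 ± 6230 CPM), ELF1 (90000 ± 9920 CPM), OCT4, the product of POU5F1 (77800 ± 16300 CPM), IRF4 (72400 ± 9540 CPM), SOX2 (49400 ± 5040 CPM), ALX4 (49300 ± 4720 CPM), IKZF2 (44900 ± 15900 CPM), FOXP1 (43900 ± 1780 CPM) and GATA1 (42700 ± 3410 CPM) lay lower. MXD1 (39700 ± 1560 CPM), SP4 (38600 ± 2190 CPM), MYC (31400 ± 588 CPM), NR4A1 (25900 ± 17.8 CPM), TCF3 (18000 ± 543 CPM) and FOXP3 (16000 ± 682 CPM) lay lowest among TFs counted on their own gene. TCF3 and MYC had the highest levels in the GFP wells, with 149 CPM for TCF3, and their rises were 120-fold and 144-fold. Targets without a gene name, which these levels leave out, held 13.5% of the counts in the MYC wells at 1 µg and 1.2% in the FOXP3 wells, against at most 0.95% in GFP wells, so the places of MYC and FOXP3 in this order are uncertain. For XBP1, KLF1 and FOXO1 the deposited quantification holds an added target sequence without a gene name, which reached 94900 ± 12800, 60100 ± 2970 and 18700 ± 2050 CPM. The annotated FOXO1 gene stayed at 26.1 ± 0.157 CPM against 25.6 ± 1.96 CPM, and the annotated XBP1 gene at 163 ± 4.06 CPM, a log2 difference of -0.43 from the GFP wells, with adjusted p = 0.884 and adjusted p = 0.576. The annotated KLF1 gene was higher, at 1.26 ± 0.434 CPM (SD, n = 4) against 0.472 ± 0.0464 CPM (adjusted p = 0.0434). The TF transcript rose with the plasmid for most TFs, with the lowest level at 0.05 µg for IKZF2 (572 ± 116 CPM). NR4A1 was already at 16300 ± 1590 CPM at 0.05 µg and was higher at 0.5 µg (55400 ± 1260 CPM) than at 1 µg, as was MXD1 (51600 ± 9400 CPM). With DESeq2 the rises of the added FOXO1 and XBP1 sequences, at 0 counts in the GFP wells, had adjusted p = 0.22 and adjusted p = 0.0977, and without GFP replicate 1 the XBP1 rise had adjusted p = 0.0773 with edgeR.

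**Figure D1:**
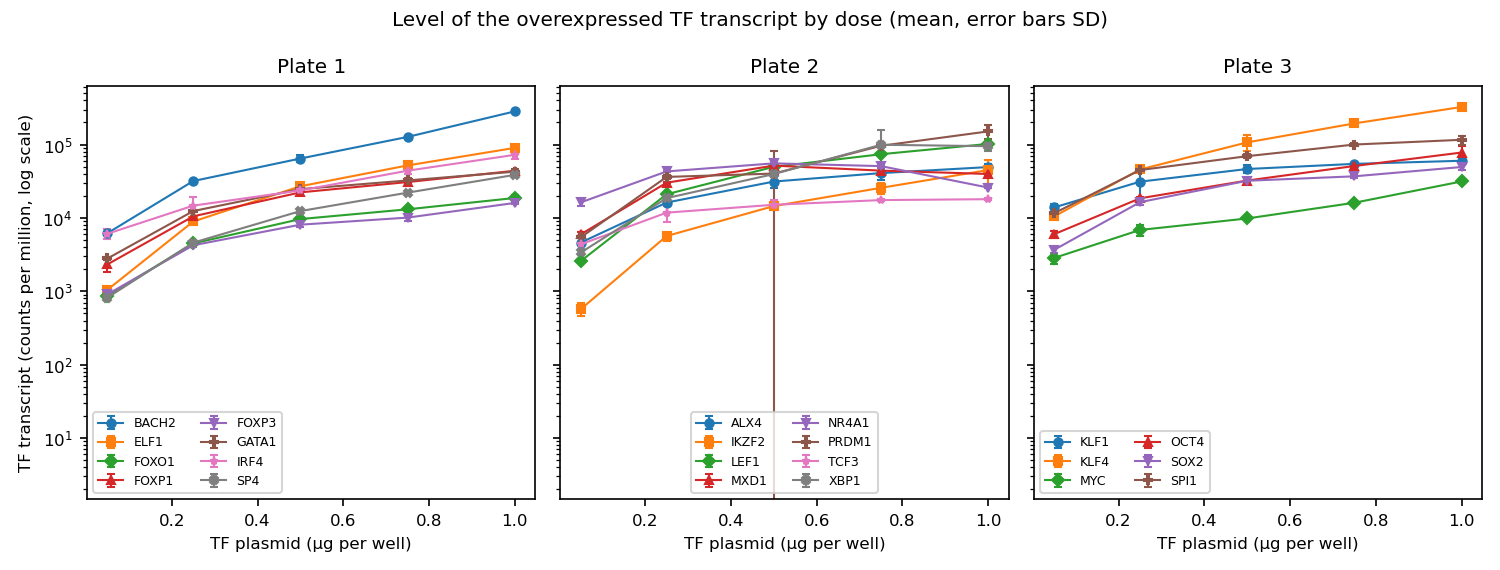
Level of each overexpressed TF transcript (CPM, log axis) against the TF plasmid (µg per well), 1 panel per plate. Points are means over the wells of a dose and error bars the SD, which for PRDM1 at 0.5 µg exceeds the mean. KLF4 is highest at 1 µg with 325000 CPM and FOXP3 lowest with 16000 CPM, where targets without a gene name are left out.

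SP4, a zinc finger TF that binds GC boxes, changed 1736 genes of 18384 tested at 1 µg, of which 1461 rose and 275 fell. Cholesterol synthesis genes moved both ways: HMGCS1, the synthase that makes HMG-CoA, was at 72.9 ± 4.49 CPM (SD, n = 2) against 112 ± 10.8 CPM, a 1.54-fold fall (adjusted p = 2.68e-09). SC5D (1.53-fold), MSMO1 (1.54-fold) and the lanosterol synthase LSS (1.36-fold) fell as well, while PCSK9, which lowers the LDL receptor, rose 5.68-fold to 1.72 ± 0.635 CPM. Of 25 tested cholesterol synthesis genes 4 rose and 12 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0709). Among 28 neural genes 4 rose and 5 fell (3 and 5 adjusted over the list alone; adjusted p = 0.723). The secretory granule protein CHGA rose 7.44-fold to 12.9 ± 1.5 CPM, and the synaptic vesicle protein SYP fell 1.65-fold. Genes at 0 counts in the GFP wells that rose most included B3GALT2, LRRTM1 and NEUROG3, at least 23.1-, 19.3- and 17.5-fold higher. A dose trend over the SP4 wells was called for 1338 genes, 1207 up and 131 down, and 918 of the genes changed at 1 µg were among them in the same direction.

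ELF1, an ETS family TF of blood cells, raised myeloid genes. Of 32 myeloid genes 16 rose and the rest did not pass, with the same count adjusted over the list alone (adjusted p = 0.000531, and adjusted p = 0.00723 with an estimated correlation). The integrin ITGAM rose 12.3-fold to 7.29 ± 0.406 CPM (SD, n = 2) from 0.59 ± 0.0718 CPM, CD33 23.4-fold, AIF1 37.1-fold and LCP1 2.91-fold. CSF2RB, the common beta chain of the GM-CSF, IL-3 and IL-5 receptors, and GIMAP6, an immune GTPase, had 0 counts in the GFP wells and were at least 29.6- and 62.4-fold higher. Of 15 T cell genes 3 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.168), among them the kinase ZAP70 (7.61-fold higher) and GATA3 (2.01-fold higher). The antigen processing genes TAPBP (2.19-fold) and ERAP1 (3.23-fold) belonged to 11 of 17 MHC class I genes that rose, also adjusted over the list alone (adjusted p = 0.000814, and adjusted p = 0.226 with an estimated correlation). Interferon-stimulated genes rose in 16 of 40 cases and fell in 3, as also adjusted over the list alone, with OAS3 6.06-fold and IFIT2 12.9-fold higher (adjusted p = 0.0176, and adjusted p = 0.543 with an estimated correlation). SNX25 fell 18-fold to 1.1 ± 0.982 CPM, and the replication factor MCM3 fell 1.59-fold to 265 ± 0.42 CPM. In all, 1818 genes changed, 1631 of them up, and 1318 had a dose trend, 1263 up and 55 down, with 962 in both. Leaving out replicate 2 of the ELF1 wells lowered the trend count to 807.

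FOXP1, a forkhead repressor, changed 271 genes at 1 µg, 105 of them lower. The largest called falls were in the inducible heat shock gene HSPA6, 21.2-fold lower at 3.9 ± 0.898 CPM (SD, n = 2) against 84.2 ± 0.555 CPM, and FERMT3, 6.33-fold lower at 0.991 ± 0.111 CPM. XKR7 (6.22-fold), ZNF750 (5.85-fold), a TF of the epidermis, and FOXJ1 (4.7-fold), a TF of ciliated cells, rose. HSPA6 and FERMT3 fell and XKR7 rose with the dose of most TFs of plates 1 and 2. Of 25 p53 targets 16 rose and 1 fell (17 and 1 adjusted over the list alone), with DDB2 1.97-fold and PHLDA3 2.32-fold higher (adjusted p = 4.39e-09, and adjusted p = 0.206 with an estimated correlation). Of 31 ATF4 targets 14 rose and 1 fell (16 and 2 adjusted over the list alone), with TRIB3 1.78-fold and CTH 1.51-fold higher (adjusted p = 0.000168, and adjusted p = 0.286 with an estimated correlation). Of 35 FOXO targets 7 rose and 4 fell (7 and 6 adjusted over the list alone; adjusted p = 0.951), and of 20 B cell genes 1 fell, also adjusted over the list alone (adjusted p = 0.859). Only 41 genes had a dose trend (26 up, 15 down), 25 of them also changed at 1 µg, and 138 genes were already higher and 77 lower at 0.05 µg (52 and 36 with offsets for GC content). At 1 µg 114 were higher and 64 lower without GFP replicate 1, and 110 higher and 57 lower without FOXP1 replicate 2. With offsets for GC content 164 genes changed, and the trend count was 9 without FOXP1 replicate 1 and 136 with no filter on low counts.

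GATA1, the erythroid and megakaryocyte GATA factor, changed 292 genes (107 lower), few of them in the blood cell lists. At 0.05 µg 144 rose and 53 fell, and position on the plate stays open. Of 22 erythroid genes only CA2 passed, and it fell 1.62-fold from 297 ± 10.5 CPM (SD, n = 2), also adjusted over the list alone (list adjusted p = 0.91). With 6 pooled GFP libraries CA2 had adjusted p = 0.0558. Among 11 megakaryocyte genes 0 passed with edgeR, while at an unadjusted p under 0.05 1 was higher and 1 lower, and DESeq2 called 0 (list adjusted p = 0.841). The replication genes E2F1 (1.66-fold) and CDC6 (1.57-fold) were among 11 of 32 G1/S genes that rose, 13 adjusted over the list alone (adjusted p = 0.000457, and adjusted p = 0.47 with an estimated correlation). DDB2 (2.07-fold) and PHLDA3 (2.25-fold) were among 11 of 25 p53 targets that rose, 14 adjusted over the list alone (adjusted p = 9.77e-06, and adjusted p = 0.361 with an estimated correlation). HSPA6 fell 19.7-fold to 4.23 ± 0.658 CPM and FERMT3 6.35-fold. The dose trend held 90 genes (46 up, 44 down), 36 of them also changed at 1 µg. At 1 µg 125 genes were higher and 62 lower without GFP replicate 1, 113 and 65 without GATA1 replicate 1, 115 and 51 with only GATA1 and GFP wells in the fit, and 106 and 71 with GC content offsets. The trend count was 35 and 57 without GATA1 replicate 1 and 2, 20 with only GATA1 and GFP wells, 157 with no filter and 56 with transcript length offsets.

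With BACH2, a basic leucine zipper repressor of B cells that binds MARE sites, p53 targets rose. So they did with FOXP1, GATA1 and FOXP3, and a shift shared over their GFP wells stays open. CDKN1A, the cell cycle inhibitor p21 (GRCh38 chromosome 6, 36676460 to 36687339), rose 3.72-fold from 54.5 ± 2.84 CPM (SD, n = 2, adjusted p = 9.24e-16). BTG2 (4.31-fold), PHLDA3 (5.32-fold), GDF15 (7.24-fold) and SESN2 (2.26-fold) rose. Of 25 p53 targets 23 rose, with 23 up and 1 down adjusted over the list alone (adjusted p = 2.3e-22, and 0.0213 with an estimated correlation). Of 30 NRF2 and MARE targets 3 rose and 11 fell, as also adjusted over the list alone, including the iron-binding pirin PIR (2-fold lower, 8.62 ± 0.851 CPM) and glutathione reductase GSR (1.41-fold lower). Their list call (adjusted p = 0.0313) was lost with an estimated correlation, with adjusted p = 0.3. Of 20 B cell genes 1 rose and 2 fell (1 and 1 adjusted over the list alone; adjusted p = 0.979), and CD24 was 1.74-fold lower. CYP4F2 rose 9.76-fold, and SYNPO2 was at 0.0968 ± 0.0522 CPM against 1.19 ± 0.166 CPM. BACH2 changed 454 genes, 279 of them up, and with GC content offsets 266 (135 up, 131 down). The dose trend held 562 genes, of which 57.1% rose, or 44.1% with GC content offsets, and 276 genes were in both.

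FOXO1, a forkhead activator, raised known FOXO targets: SESN1 2.01-fold to 68.2 ± 0.0868 CPM (SD, n = 2), CITED2 1.74-fold and BCL6 2.28-fold. KLF2, YPEL3 and CDKN1A rose 3.69-, 1.87- and 2.13-fold, and CDKN1A more with BACH2 and FOXP3 of this plate. Of 35 FOXO targets 14 rose and 2 fell (15 and 4 adjusted over the list alone; adjusted p = 0.000515, and adjusted p = 0.177 with an estimated correlation). Among 15 T cell genes 0 passed with edgeR and 0 with DESeq2, while 1 was higher at an unadjusted p under 0.05 (list adjusted p = 0.855). HSPA6 fell 43.5-fold to 1.92 ± 0.246 CPM and FERMT3 6.28-fold. FOXO1 changed 480 genes, 122 of them lower, 633 had a dose trend (526 up, 107 down) and 258 were in both. The trend took in 3.44% of tested genes, against 2.14% without FOXO1 replicate 1, and held 310 rising and 59 falling genes with a slope over the logarithm of the dose.

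FOXP3, the forkhead TF of regulatory T cells, changed FOXO target genes in both directions. CDKN1A rose 2.85-fold to 155 ± 10.8 CPM (SD, n = 2), while SESN3 fell 2.19-fold, the cell cycle inhibitor CDKN1B 1.46-fold, CCNG2 1.43-fold and the pro-apoptotic BCL2L11 1.58-fold. Of 35 FOXO targets 8 rose and 12 fell (9 and 12 adjusted over the list alone; adjusted p = 0.474). Of 15 T cell genes 2 rose, also adjusted over the list alone (adjusted p = 0.415). The scavenger receptor gene SSC5D rose 45.9-fold to 21.7 ± 4.32 CPM, IP6K3 36.8-fold, and KLHDC7A, at 0 counts in the GFP wells and higher with all 8 TFs of the plate, at least 22.5-fold. DDB2 (2.24-fold) and PHLDA3 (3.52-fold) were among 20 of 25 p53 targets that rose, with 20 up and 1 down adjusted over the list alone (adjusted p = 4.53e-12, and adjusted p = 0.131 with an estimated correlation). FOXP3 changed 802 genes, 604 of them up, 681 had a dose trend (601 up, 80 down) and 420 were in both. GC content offsets lowered the first count to 463 and the trend from 3.7% to 2.13% of tested genes, and 309 genes had a trend without FOXP3 replicate 1.

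IRF4, an interferon regulatory factor of lymphocytes, changed interferon-stimulated genes in both directions. ISG20, an RNA exonuclease, rose 8.34-fold to 14.6 ± 5.01 CPM (SD, n = 2), IRF7 3.1-fold, the RNA sensor DHX58 5.07-fold and IFIT2 9.78-fold, whereas IFIT5 fell 1.73-fold and HERC6 2.13-fold. Of 40 interferon-stimulated genes 9 rose and 5 fell, as also adjusted over the list alone (adjusted p = 0.278). The peptide transporter TAP1 rose 1.47-fold among 10 of 17 MHC class I genes that rose, also adjusted over the list alone (adjusted p = 0.00603, and adjusted p = 0.326 with an estimated correlation). LMAN1L and the cytokine OSM, at 0 counts in the GFP wells, were at least 30.8- and 18-fold higher, and HSPA6 was 72.5-fold lower. IRF4 changed 951 genes (819 up, 132 down; 523 with GC content offsets), 852 had a dose trend (743 up, 109 down) and 533 were in both. Leaving out IRF4 replicate 1 lowered the trend count to 529.

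On plate 2 the 18153 tested genes were compared with GFP wells of which replicate 1 stood apart: the GFP libraries correlated at 0.852, where the median over all libraries was 0.9915, and with the plate median replicate 1 correlated at 0.875 and replicate 2 at 0.985. Another 6 pairs of wells of this plate correlated at under 0.95, and the library less like the plate median was IKZF2 at 1 µg replicate 1, PRDM1 at 1 µg replicate 2 and at 0.5 µg replicate 2, XBP1 at 0.75 µg replicate 1, and TCF3 at 0.25 µg replicate 1 and at 0.05 µg replicate 1. Cytoplasmic ribosomal protein genes lay lower than in the GFP wells for all 8 TFs, with a median log2 change over TFs of -1.48, and of -0.13 without GFP replicate 1.

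IKZF2 (Helios), a zinc finger TF of T cells, raised DHRS2, a short-chain dehydrogenase gene (GRCh38 chromosome 14, 23630115 to 23645639), 55.3-fold from 4.31 ± 1.67 CPM (SD, n = 2; adjusted p = 2.99e-15). BNIP5 reached 9.66 ± 0.294 CPM and NXF3, an RNA export factor, 6.01 ± 1.94 CPM, against 0.0224 and 0.0447 CPM. HSPA6 fell 30-fold and its co-chaperone gene DNAJB1 4.26-fold to 106 ± 11.4 CPM. DDB2, 2.47-fold higher, was among 5 of 25 p53 targets that rose, with 7 up and 2 down adjusted over the list alone (adjusted p = 0.00433, and adjusted p = 0.378 with an estimated correlation). Among 17 T cell genes 0 passed with edgeR and 0 with DESeq2, 6 being lower at an unadjusted p under 0.05. The list passed camera as lower (adjusted p = 0.0223), but with adjusted p = 0.179 with an estimated correlation and 0.473 without the libraries that stood apart. Among 19 B cell genes 0 passed with edgeR and 0 with DESeq2, with 1 lower at an unadjusted p under 0.05 (list adjusted p = 0.622). IKZF2 changed 451 genes (313 up, 138 down) and 625 had a dose trend (476 up, 149 down). The count was 906 without GFP replicate 2, 866 without IKZF2 replicate 2, 55 with only IKZF2 and GFP wells and 1144 with 6 pooled GFP libraries, and it fell from 2.48% to 1.33% of tested genes without IKZF2 replicate 1. The trend count was 75 without IKZF2 replicate 1, 55 with only IKZF2 and GFP wells and 1026 with no filter.

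LEF1, the HMG box TF of Wnt signalling, changed 630 genes (280 up, 350 down). XKR7 rose 12.7-fold to 4.81 ± 0.172 CPM (SD, n = 2) and the chloride channel gene BEST1 6.73-fold to 28.3 ± 7.27 CPM, and FERMT3 fell 26.2-fold from 14.9 ± 3.79 CPM. Of 32 Wnt targets 3 fell and the rest did not pass, also adjusted over the list alone (adjusted p = 0.252). Among 17 T cell genes 0 passed with edgeR and 0 with DESeq2, with 1 lower at an unadjusted p under 0.05 (list adjusted p = 0.82). Of 34 FOXO targets 1 rose and 6 fell (2 and 9 adjusted over the list alone), BCL6 2.31-fold (adjusted p = 0.00696, and adjusted p = 0.024 with an estimated correlation). CDC6 rose 1.83-fold among 32 G1/S genes of which 7 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.281 with an estimated correlation). DDB2 (3.35-fold) and AEN (2.53-fold) rose among 25 p53 targets of which 6 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.000814, and adjusted p = 0.293 with an estimated correlation). A trend with dose was seen in 210 genes, of which 67.1% rose, or 78.6% with GC content offsets, and 121 of them were in both. Leaving out GFP replicate 1, GFP replicate 2 or LEF1 replicate 1 gave 220, 2895 and 256 genes at 1 µg, leaving out LEF1 replicate 2 gave 116 up and 67 down, and no filter gave 1172. For the trend the count was 33 and 26 without LEF1 replicate 1 and 2, 323 over the logarithm of the dose and 462 without the libraries that stood apart.

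NR4A1, an orphan nuclear receptor, changed 112 genes (36 up, 76 down) at 1 µg and 1151, 1105 and 898 at 0.25, 0.5 and 0.75 µg. The cytokine gene CLCF1 rose 6.61-fold to 3.33 ± 0.472 CPM (SD, n = 2) and CRPPA 4.85-fold. HSPA6 fell 93.7-fold, DNAJB1 5.48-fold, FERMT3 15-fold and CCN1, a secreted matrix protein, 2.11-fold to 10 ± 0.35 CPM. Of 32 immediate early genes 4 fell, 10 adjusted over the list alone (adjusted p = 2.87e-05, and adjusted p = 0.153 with an estimated correlation). Of 15 steroid synthesis genes 1 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.899). Only 11 genes had a dose trend (2 up, 9 down, and 3 up and 4 down with transcript length offsets), 6 of them in both. The 1 µg count was 25 and 2180 without GFP replicate 1 and 2, 34 and 28 without NR4A1 replicate 1 and 2, 628 with no filter, and 51 with only NR4A1 and GFP wells. There were 104 up and 125 down without the libraries that stood apart (794 genes at 0.25 µg), 50 and 143 with DESeq2, and 71 and 145 with pooled GFP libraries. The trend count was 2 and 1 without NR4A1 replicate 1 and 2, 23 over the logarithm of the dose, 65 with no filter, 4 with only NR4A1 and GFP wells, 121 without the libraries that stood apart and 21 with DESeq2.

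PRDM1 (Blimp-1), a repressor of B cell programmes that drives plasma cell differentiation, changed 1707 genes (973 up, 734 down). Immediate early genes rose, EGR1 5.94-fold to 79.5 ± 9.11 CPM (SD, n = 2), FOS 4.41-fold, ZFP36 4.6-fold and KLF10 2.95-fold, in 13 of 33 cases with 3 falls (17 and 3 adjusted over the list alone; adjusted p = 2.72e-05, and adjusted p = 0.171 with an estimated correlation). The junction genes CLDN6 (4.7-fold) and CDH3 (2.21-fold) rose among 10 of 33 epithelial genes that rose, with 11 up and 1 down adjusted over the list alone (adjusted p = 0.0278, and adjusted p = 0.129 with an estimated correlation). PLK3 (6.23-fold) and DDB2 (2.75-fold) rose among 25 p53 targets of which 10 rose and 3 fell (15 and 4 adjusted over the list alone; adjusted p = 0.000317, and adjusted p = 0.252 with an estimated correlation). Of 37 interferon-stimulated genes 2 rose and 3 fell (2 and 1 adjusted over the list alone; adjusted p = 0.741), DHX58 being 9.51-fold higher, and of 19 B cell genes 1 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.979). CYP4F2, at 0 counts in the GFP wells, was at least 15.6-fold higher, and the ubiquitin ligase TRIM67 was at 4.94 ± 3.92 CPM against 0.0447 CPM. The dose trend held 1533 genes (978 up, 555 down), 947 of them in both. None of the PRDM1 genes named here passed when only PRDM1 and GFP wells were fitted, where 7 genes were called at 1 µg and 8 in the trend. Leaving out PRDM1 replicate 1 gave 2920 genes at 1 µg and 2988 in the trend, and leaving out PRDM1 replicate 2 gave 802 in the trend.

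XBP1, the TF of the unfolded protein response, changed 47 genes at 1 µg (27 up, 20 down). FERMT3 fell 20.2-fold to 0.731 ± 0.127 CPM (SD, n = 2) and ZNF79 rose 3.15-fold to 22.7 ± 1.85 CPM, but both had adjusted p = 0.146 when only XBP1 and GFP wells were fitted. HSPA5, the ER chaperone BiP, was 1.54-fold lower than its 512 ± 63.4 CPM in the GFP wells (adjusted p = 0.0414). Its call was lost with no filter (adjusted p = 0.318), with transcript length offsets (adjusted p = 0.0786), with only XBP1 and GFP wells (adjusted p = 0.375), without GFP replicate 1 or 2 (adjusted p = 0.116 and adjusted p = 0.0567) and without XBP1 replicate 1 or 2 (adjusted p = 0.288 and adjusted p = 0.389). HSPA5 was the only of 50 ER folding and secretion genes that passed, and 11 fell adjusted over the list alone. As a list they were lower (adjusted p = 5.19e-06, and adjusted p = 0.0518 with an estimated correlation). Of 31 ATF4 targets 1 rose (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.482). The split was 39 up and 151 down among the 190 genes of DESeq2, and 23 up and 36 down with GC content offsets. The count was 9 and 2206 without GFP replicate 1 and 2, 13 and 12 without XBP1 replicate 1 and 2, 715 with no filter, 0 with only XBP1 and GFP wells, 152 with pooled GFP libraries, and 98 up and 99 down without the libraries that stood apart. A dose trend was called for 106 genes (66 up, 40 down), 25 of them in both, and this count was 8 and 36 without XBP1 replicate 1 and 2, 68 over the logarithm of the dose, 247 with no filter, 1 with only XBP1 and GFP wells and 291 without the libraries that stood apart.

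ALX4, a homeodomain TF of craniofacial and limb mesenchyme, changed 1231 genes (745 up, 486 down). ACTA2, smooth muscle actin, rose 7.78-fold from 3.93 ± 0.382 to 31.1 ± 3.92 CPM (SD, n = 2), and of 31 mesenchyme and neural crest genes 3 rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.409). Of 27 neural genes 4 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.943), with the Notch effector HES5 2.54-fold lower. ID4 (3.03-fold), NRARP (1.75-fold) and HES5 were among 12 of 21 ID and Notch feedback genes that fell, with 1 up and 12 down adjusted over the list alone (adjusted p = 0.000183, and adjusted p = 0.125 with an estimated correlation). GRHL3, a TF of the epidermis, rose 7.83-fold among 4 of 33 epithelial genes that rose, also adjusted over the list alone (adjusted p = 0.0199, adjusted p = 0.11 with an estimated correlation, and adjusted p = 0.0896 without the libraries that stood apart). CDHR4 and the chemokine receptor CX3CR1, at 0 counts in the GFP wells, were at least 17.9- and 17.6-fold higher. The dose trend held 826 genes (732 up, 94 down), 435 of them in both. Leaving out GFP replicate 1, GFP replicate 2 or ALX4 replicate 1 gave 426, 3357 and 685 genes at 1 µg, and leaving out ALX4 replicate 2 gave 289 up and 67 down. For the trend the count was 307 and 127 without ALX4 replicate 1 and 2, and 1379 without the libraries that stood apart.

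TCF3, which encodes the E proteins E12 and E47, raised epithelial cadherin genes. CDH1, E-cadherin, rose 6.48-fold from 4.73 ± 2.1 to 32.2 ± 1.32 CPM (SD, n = 2; adjusted p = 2.02e-10), CDH3 6.02-fold, the claudin CLDN1 5.82-fold and the keratin KRT17 29-fold. In all, 10 of 33 epithelial genes rose and the rest did not pass, also adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.00394 with an estimated correlation). Of 21 ID and Notch feedback genes 5 rose and 5 fell (5 and 7 adjusted over the list alone; adjusted p = 0.795), LFNG being 12.4-fold higher and HEY1 2.13-fold lower. Of 14 E-box targets of muscle 4 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.154), with M-cadherin, CDH15, 36.4-fold higher at 17 ± 2.53 CPM. Of 19 B cell genes 1 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.752), and the complement receptor CR2 rose 11.6-fold to 33 ± 2.13 CPM. Ribosome biogenesis genes fell in 15 of 55 cases, 19 adjusted over the list alone (adjusted p = 1.43e-06, and adjusted p = 0.0474 with an estimated correlation). TACR1, XIRP1, the mucin MUC5AC and the dopamine transporter SLC6A3, at 0 counts in the GFP wells, were at least 38.4-, 35.4-, 34- and 26.1-fold higher. TCF3 changed 1797 genes (1115 up, 682 down) and 1909 had a dose trend (1097 up, 812 down, and 1374 up and 157 down with GC content offsets), with 538 in both. Leaving out GFP replicate 1, GFP replicate 2, TCF3 replicate 1 or TCF3 replicate 2 gave 801, 3762, 1014 and 949 genes at 1 µg, and with only TCF3 and GFP wells the share of tested genes called fell from 9.9% to 2.01%. For the trend the count was 305 and 5744 without TCF3 replicate 1 and 2, 56 with only TCF3 and GFP wells and 971 without the libraries that stood apart.

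MXD1, a MAX partner that opposes MYC, changed 41 genes (12 up, 29 down) at 1 µg, and 1243, 1197 and 316 at 0.25, 0.5 and 0.75 µg (576 and 593 at 0.25 and 0.5 µg without the libraries that stood apart). HSPA6 fell 76.1-fold to 0.745 ± 0.159 CPM (SD, n = 2), FERMT3 8.21-fold and DNAJB1 4.22-fold. Among 55 ribosome biogenesis and MYC target genes 0 passed with edgeR, 9 were lower at an unadjusted p under 0.05, 3 were lower with DESeq2, and 1 fell adjusted over the list alone. As a list they passed camera as lower (adjusted p = 0.000685, and adjusted p = 0.18 with an estimated correlation). Among 32 G1/S genes 0 passed with edgeR or DESeq2, and 2 were higher and 2 lower at an unadjusted p under 0.05 (list adjusted p = 0.976). The dose trend held 58 genes (27 up, 31 down), 11 of them in both. The 1 µg count was 11 and 2443 without GFP replicate 1 and 2, 4 and 16 without MXD1 replicate 1 and 2, 736 with no filter, 4 with only MXD1 and GFP wells, 139 without the libraries that stood apart, 200 with DESeq2 (36 up, 164 down), 106 with GC content offsets and 107 with pooled GFP libraries. The trend count was 15 and 7 without MXD1 replicate 1 and 2, 135 with no filter and 272 without the libraries that stood apart.

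On plate 3, where 19106 genes were tested, KLF4 raised epithelial genes and alpha-globin genes. The keratin KRT17 rose 142-fold to 62.7 ± 16.8 CPM (SD, n = 2), the cadherins CDH1 2.78-fold and CDH3 4.79-fold, and the plakins PPL 6.82-fold and DSP 2.47-fold. Of 35 epithelial and keratinocyte genes 25 rose and 1 fell, as also adjusted over the list alone (adjusted p = 1.79e-05, and adjusted p = 0.0198 with an estimated correlation). HBA1 (GRCh38 chromosome 16, 176680 to 177522) rose 136-fold to 487 ± 105 CPM and its near-identical neighbour HBA2 (172876 to 173710) 492-fold, and the division of reads between them is uncertain. They were among 24 erythroid genes of which 11 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.0469, adjusted p = 0.115 with an estimated correlation and adjusted p = 0.0714 without the libraries that stood apart). Of 31 pluripotency genes 14 rose and 3 fell (16 and 3 adjusted over the list alone), CD9 2.91-fold and UTF1 2.64-fold, and the list did not pass (adjusted p = 0.0631, and 0.0485 without the libraries that stood apart). Creatine kinase CKM rose 45.4-fold among 17 muscle genes of which 9 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.00208, and adjusted p = 0.024 with an estimated correlation). E2F1 (2.33-fold) and MCM10 (2.24-fold) were among 32 G1/S genes of which 3 rose and 19 fell, as also adjusted over the list alone (adjusted p = 0.000153, and adjusted p = 0.396 with an estimated correlation). The amino acid transporter SLC6A19, MUC2 and LGALS7B, at 0 counts in the GFP wells, were at least 135-, 33.4- and 30.6-fold higher, and the synaptic protein CPLX2 reached 39.2 ± 3.39 CPM from 0.0732 CPM. KLF4 changed 3385 genes (2596 up, 789 down, and 2858 up and 434 down with GC content offsets) and 1879 had a dose trend, 1473 of them rising, with 1289 in both. Leaving out KLF4 replicate 1 lowered the trend count to 1252.

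KLF1, the erythroid Krüppel-like factor, raised globin and other erythroid genes. HBA1 rose 115-fold to 411 ± 32.7 CPM (SD, n = 4) from 3.57 ± 1.07 CPM (n = 2), HBA2 by 8.57 on the log2 scale, and the embryonic zeta globin HBZ (GRCh38 chromosome 16, 152687 to 154503) 71.3-fold to 13.4 ± 1.55 CPM. The anion exchanger SLC4A1 rose 3.89-fold and the membrane skeleton protein EPB41 1.42-fold. Of 24 erythroid genes 12 rose and the rest did not pass, also adjusted over the list alone (adjusted p = 0.00583, and adjusted p = 0.0191 with an estimated correlation). Of 35 epithelial genes 27 rose and 2 fell (29 and 2 adjusted over the list alone), KRT17 53.7-fold, CDH3 6.18-fold, DSP 2.56-fold and EVPL 19.2-fold (adjusted p = 1.17e-06, and adjusted p = 0.007 with an estimated correlation). MCM10 (2.45-fold) and MCM2 (2.64-fold) were among 32 G1/S genes of which 1 rose and 24 fell, as also adjusted over the list alone (adjusted p = 3.13e-08, and adjusted p = 0.196 with an estimated correlation). The lymphoid genes CD7 (69.4-fold, to 25.7 ± 2.29 CPM) and LCK (47.9-fold) rose among 18 T cell genes of which 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.288 with an estimated correlation). Tyrosine hydroxylase, TH, and SLC6A19 had 0 counts in the GFP wells and were at least 137- and 112-fold higher, and the sarcoglycan SGCA and the proteoglycan BGN reached 43.4 ± 3.82 and 33.7 ± 9.21 CPM from 0.0366 and 0.0361 CPM. KLF1 changed 3193 genes (2770 up, 423 down) and 1900 had a dose trend, 1659 of them rising, with 1042 in both. The 0.25 µg library of replicate 4 stood apart, with a correlation of 0.914 with its replicates.

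SOX2, an HMG box TF of pluripotent and neural progenitor cells, changed 2751 genes (2084 up, 667 down). Neuronal genes moved both ways: the tubulin TUBB3 rose 6.1-fold to 118 ± 35.4 CPM (SD, n = 2), SYP 2.01-fold, and the RNA-binding protein ELAVL3 reached 6.57 ± 0.174 CPM from 0.0721 CPM, while the neural TFs POU3F2 fell 2.84-fold and PAX6 1.59-fold. Of 30 neural genes 9 rose and 4 fell, as also adjusted over the list alone (adjusted p = 0.764). Of 31 pluripotency genes 7 rose and 6 fell, as also adjusted over the list alone (adjusted p = 0.804), among them KLF4 (3.23-fold lower), TBX3 (1.87-fold lower) and the let-7 inhibitor LIN28B (1.96-fold lower). The calcium channel RYR1 rose 15-fold among 17 muscle genes of which 9 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.00914, and adjusted p = 0.0645 with an estimated correlation). ITGAM rose 35.6-fold among 36 myeloid genes of which 12 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.0235, and adjusted p = 0.281 with an estimated correlation). With dose, ITGAM rose for all 6 TFs of the plate. Vimentin, VIM (2.25-fold), and FOXC1 (3.26-fold) were among 33 mesenchyme and neural crest genes of which 6 rose and 15 fell, as also adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.153 with an estimated correlation). The serotonin receptor HTR5A, at 0 counts in the GFP wells, was at least 39.2-fold higher. A dose trend was called for 2682 genes (2105 up, 577 down), 1861 of them in both, and for 1773 without SOX2 replicate 2.

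OCT4, the POU domain TF of pluripotent cells, lowered immediate early and stress genes. ATF3 fell 2.52-fold to 61.8 ± 1.14 CPM (SD, n = 2), JUN 2.71-fold and EGR3 3.65-fold, among 33 immediate early genes of which 1 rose and 21 fell (1 and 23 adjusted over the list alone; adjusted p = 4.39e-09, and adjusted p = 0.0285 with an estimated correlation). CEBPB (2.96-fold) and DDIT3 (2.06-fold) were among 31 ATF4 targets of which 3 rose and 18 fell (3 and 19 adjusted over the list alone; adjusted p = 6.9e-07, and adjusted p = 0.071 with an estimated correlation). HES1 fell 2.51-fold among 21 ID and Notch feedback genes of which 1 rose and 16 fell (1 and 17 adjusted over the list alone; adjusted p = 3.29e-05, and adjusted p = 0.181 with an estimated correlation). Of 31 pluripotency genes 5 rose and 7 fell (6 and 8 adjusted over the list alone; adjusted p = 0.974), SALL4 being 2.33-fold higher, KLF4 2.36-fold lower, and the NODAL inhibitor LEFTY2 at 2.67 ± 0.423 CPM against 0.11 CPM. Of 17 germline genes 4 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.276), with TEX14 4.33-fold higher. POU5F1B, a retrogene that shares sequence with the transfected POU5F1, was 1070-fold higher, a value that reads of the plasmid can give. PLVAP, HHATL, the R-spondin RSPO2 and coagulation factor F11, at 0 counts in the GFP wells, were at least 27.6-, 21.8-, 16.3- and 14.8-fold higher. OCT4 changed 1782 genes (1382 up, 400 down) and 1645 had a dose trend, 1458 of them rising (825 in all without OCT4 replicate 2), with 1011 in both.

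MYC raised ribosome biogenesis genes: RRP9 rose 2.44-fold to 117 ± 0.32 CPM (SD, n = 2), RRP12 1.99-fold, MYBBP1A 1.94-fold, PES1 1.89-fold and UTP4 1.81-fold. Of 55 ribosome biogenesis and MYC target genes 27 rose and 3 fell (28 and 3 adjusted over the list alone; adjusted p = 4.53e-08, and adjusted p = 0.35 with an estimated correlation). MCM5 (1.68-fold), CLSPN (1.59-fold) and E2F2 (1.77-fold) were among 32 G1/S genes of which 12 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.646 with an estimated correlation). The glucose transporter SLC2A3 fell 3.97-fold among 29 hypoxia and glycolysis genes of which 2 rose and 17 fell (2 and 19 adjusted over the list alone; adjusted p = 5.83e-05, and adjusted p = 0.455 with an estimated correlation). DERL3, a factor of ER-associated degradation, rose 8.89-fold to 74.7 ± 2.16 CPM, while its list of 50 ER genes held 5 that rose and 15 that fell (6 and 16 adjusted over the list alone; adjusted p = 0.0297 as lower, and adjusted p = 0.51 with an estimated correlation). The cohesin gene SMC1B rose 14.7-fold, the glucagon receptor GCGR reached 5.15 ± 0.209 CPM from 0.108 CPM, and ANKRD1 fell 7.78-fold, as it did past the threshold with all 6 TFs of the plate. MYC changed 944 genes, of which 63.7% rose, or 74.9% with GC content offsets, and 1526 with pooled GFP libraries. The dose trend held 586 genes, of which 70% rose, or 80.3% with GC content offsets, and 288 without MYC replicate 1. Without MYC replicate 2 it held 259 rising and 118 falling genes.

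SPI1 (PU.1), the ETS TF of myeloid and B cells, raised genes of both lineages. The kinase BTK rose 11.6-fold to 8.52 ± 0.777 CPM (SD, n = 4) from 0.727 ± 0.11 CPM (n = 2), AIF1 26.7-fold and LAPTM5 8.34-fold, and CSF2RB, at 0 counts in the GFP wells, at least 42.1-fold. Of 36 myeloid genes 14 rose and the rest did not pass, also adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.129 with an estimated correlation). EBF1 (20.6-fold, to 27.8 ± 3.81 CPM) and the recombinase gene RAG1 (3.19-fold) were among 7 of 19 B cell genes that rose, also adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.0562 with an estimated correlation). Interferon-stimulated genes rose in 19 of 37 cases, 20 adjusted over the list alone (adjusted p = 1.32e-06, and adjusted p = 0.024 with an estimated correlation), OAS3 11.3-fold, IFIT2 39.1-fold and TRIM22 17.4-fold. The cytokine IL1B and the apoptosis inhibitor BIRC7, at 0 counts in the GFP wells, were at least 36.1- and 21.4-fold higher. SPI1 changed 1634 genes (1340 up, 294 down, and 1616 up and 137 down with GC content offsets) and 1814 had a dose trend (1552 up, 262 down), with 787 in both.

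**Figure D2:**
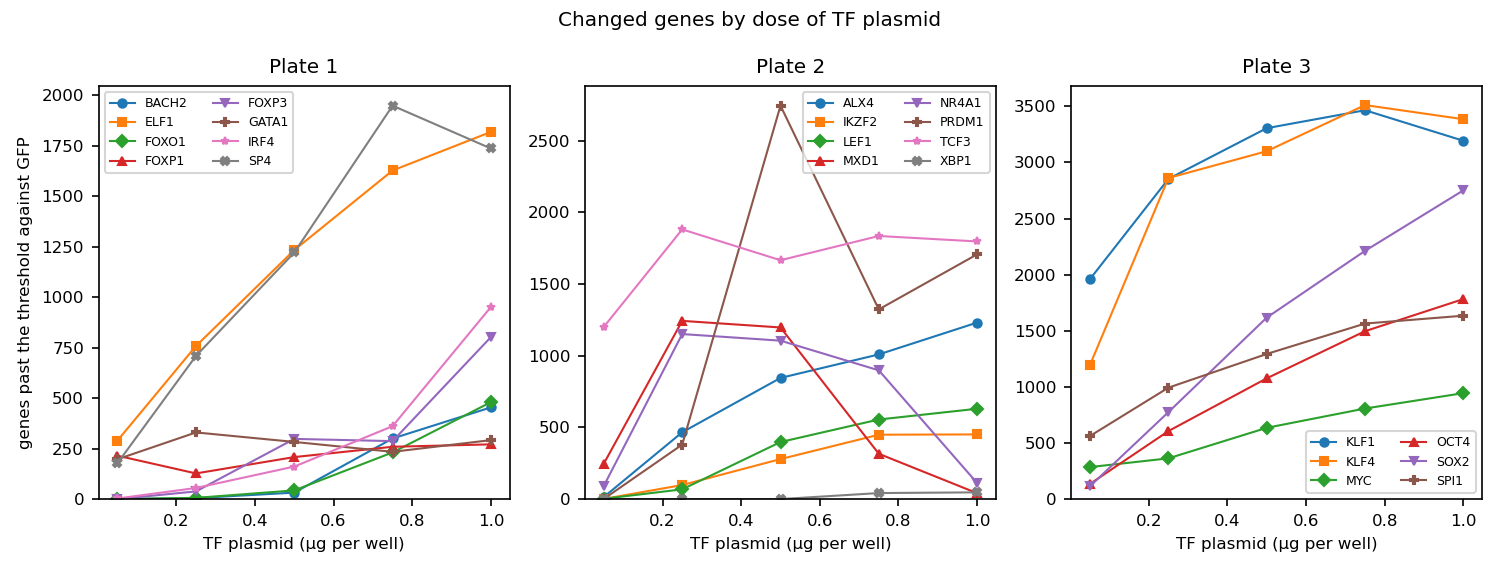
Number of genes past the threshold against GFP (adjusted p under 0.05 and at least 2-fold) by TF plasmid (µg per well), 1 panel per plate with its own vertical axis. On plate 3 the KLF1 and KLF4 counts rise from 1958 and 1191 at 0.05 µg to 3193 and 3385 at 1 µg, while on plate 2 the MXD1 count falls from 1243 at 0.25 µg to 41 at 1 µg (from 576 to 139 without the libraries that stood apart, not drawn).

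Gene sets of related TFs were compared directly at 1 µg. Between KLF4 and KLF1 1136 genes differed, 545 higher with KLF4 and 591 lower. RFPL4B was at 2.36 ± 0.288 CPM with KLF4 (SD, n = 2) and 0.102 ± 0.134 CPM with KLF1 (n = 4), 21.8-fold higher, TACR1 16.2-fold and the histone gene H2BC8 15.9-fold higher, while the receptor TNFRSF18 was 9.07-fold lower. PERCC1 and LCN6 were at 0.0599 ± 0.0847 and 0.0299 ± 0.0423 CPM with KLF4 and at 4.41 ± 1.08 and 2.07 ± 0.551 CPM with KLF1. Between FOXP1 and FOXO1 152 genes differed, 48 higher with FOXP1 and 104 lower. ZNF750 was 6.05-fold and the inhibin subunit INHBE 4.89-fold higher with FOXP1 (13.5 ± 0.359 against 2.78 ± 0.637 CPM), and ESM1 51.6-fold and the BMP antagonist GREM2 12.6-fold lower. These wells lie in different columns of plate 1, as do those of FOXP3 and FOXP1. Between FOXP3 and FOXP1 1.13% of tested genes differed, 22 lower with FOXP3 and the rest higher, among them TCEAL7, 45.7-fold higher at 25.8 ± 1.97 CPM, and SLC9A9 (2.82-fold) and STMND1 (2.56-fold), which were lower. The FOXP1 against FOXO1 count was 88 and 83 without FOXP1 replicate 1 and 2, 261 with no filter and 98 with transcript length offsets. The FOXP3 against FOXP1 count was 109 and 110 without FOXP1 replicate 1 and 2, 131 without either FOXP3 replicate and 129 with transcript length offsets.

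The share of the 1 µg response that was present at 0.25 µg differed between TFs. This relative response is the median log2 change at 0.25 µg divided by the median at 1 µg, each gene signed by its mean change, over genes that responded to the TF (adjusted p under 0.05 over the 5 doses against GFP and a mean log2 change of at least 1 in size). The SD is over values computed from each replicate number alone. It was lowest for BACH2 (0.398 ± 0.112 over 61 genes, SD, n = 2), FOXP3 (0.487 ± 0.034), IRF4 (0.507 ± 0.049), SOX2 (0.529 ± 0.001), FOXO1 (0.555 ± 0.131) and OCT4 (0.568 ± 0.02). ELF1 (0.617 ± 0.002), SP4 (0.645 ± 0.011), PRDM1 (0.726 ± 0.025), SPI1 (0.775 ± 0.032, n = 4), ALX4 (0.791 ± 0.007), LEF1 (0.807 ± 0.026), FOXP1 (0.808 ± 0.013), IKZF2 (0.839 ± 0.009) and MYC (0.839 ± 0.003) lay between. KLF1 (0.888 ± 0.191, n = 4), GATA1 (0.894 ± 0.119), TCF3 (0.924 ± 0.152) and KLF4 (0.944 ± 0.024, over 2617 genes) were higher, and MXD1 (1.421 ± 0.068) and NR4A1 (1.581 ± 0.12) above 1. XBP1 had fewer than 20 responding genes and was left out. A permutation test of the single-replicate values between TFs gave p = 1e-05, the smallest that 100000 resamples can give, and TFs held 94.3% of the sum of squares. Within plates the permutation test gave p = 0.00094, 5e-05 and 0.0124 on plates 1 to 3. It takes no account of GFP error or position. On plate 1 the 4 TFs in columns 2 to 6 (0.617 to 0.894) all lay above the 4 in columns 7 to 11 (0.398 to 0.555). The value was 0.555 and 1.432 for IKZF2 without GFP replicate 1 and 2 and 0.501 without IKZF2 replicate 2, 1.145 for PRDM1 without GFP replicate 2, and 1.709 for TCF3 without TCF3 replicate 2. With pooled GFP libraries it was 0.638 for BACH2, and over dose trend genes alone it was lower for all TFs with a value but MXD1 (1.591), from 0.092 for BACH2 to 0.347 for GATA1, 0.505 for KLF4, 0.596 for TCF3 and 0.598 for KLF1.

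**Figure D3:**
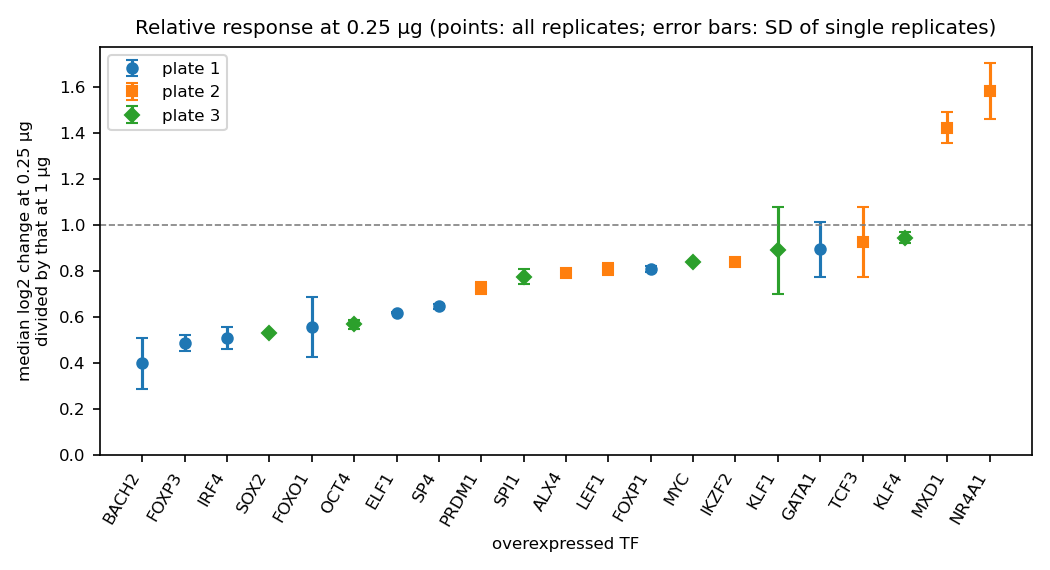
Relative response of each TF at 0.25 µg (share of the change at 1 µg), computed as the median log2 change at 0.25 µg divided by that at 1 µg. Points use all replicates, and error bars are the SD of values from single replicates. BACH2 is lowest with 0.398 and NR4A1 highest with 1.581.

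Across the 22 TFs the number of genes changed at 1 µg had no clear relation to the level of the TF transcript as counted here, which for MYC and FOXP3 leaves out targets without a gene name. Pearson's r was 0.206 (permutation p = 0.358, adjusted p = 0.827 over a family of 30) and Spearman's rho 0.274 (permutation p = 0.214, adjusted p = 0.827). KLF4, with the highest transcript level, changed 3385 genes, but KLF1 changed 3193 at 60100 CPM, and BACH2 changed 454 at 283000 CPM. Without KLF4 and BACH2, the TFs farthest from the median, r was 0.15 (permutation p = 0.529). Within plates r was 0.035, 0.052 and 0.541 on plates 1 to 3, with exact p = 0.914, 0.9 and 0.247.

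Responses of TF pairs were compared by the correlation of their dose slopes, across genes with a dose trend in either TF, which use no GFP library. Genes are not independent replicates, so no p is given. KLF1 and KLF4, both Krüppel-like factors, had r = 0.419, rank 9 among all pairs. OCT4 and SOX2, partners in pluripotent cells, had r = 0.404, rank 13. KLF4 and SP4 had r = 0.306, IRF4 and PRDM1 0.207, LEF1 and SOX2 0.201, FOXO1 and FOXP3 0.18, and MXD1 and MYC, which compete for MAX, 0.104. ELF1 and SPI1, both ETS factors, had r = 0.046, KLF1 and SP4 0.03, FOXP1 and FOXP3 0.01, FOXO1 and FOXP1 -0.024 and GATA1 and KLF1 -0.072. Over all genes tested for both r was 0.277 for ELF1 and SPI1, 0.231 for KLF1 and SP4, 0.291 for FOXO1 and FOXP3 and -0.024 for MXD1 and MYC, with a median of 0.104 for the other pairs. The other pairs had a median of 0.115, from -0.255 to 0.681, and a median of 0.185 on the same plate and 0.099 on different plates. MXD1 with NR4A1 (0.681 over 64 genes, 0.172 over all) and ALX4 with SOX2 (0.607) had the highest values. Simulated unchanged TFs gave 0.00142 for slopes, and 0.489 for changes against shared GFP wells, which were therefore not used here.

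Genes that followed the dose of most TFs on a plate included the inducible chaperones. On plate 1 DNAJB1, HSPA1A, HSPA1B and HSPA6 fell with the dose of 7 of 8 TFs, the cilium gene ROPN1L rose with all 8, and XKR7 and H4C14 rose with 7. On plate 2 DNAJB1 and HSPA1B fell with 7 of 8 TFs and HSPA6 and FERMT3 with 6, and on plate 3 ITGAM, ANGPTL4, ETV5 and ELOVL3 were among 13 genes that rose with all 6. At 1 µg against the GFP wells, FERMT3 was lower with all 8 TFs of plate 2, and on plate 3 HHATL, RSPO2 and ITGAM were higher with all 6. Reads of HSPA1A and HSPA1B cannot be told apart reliably. Of 20 tested heat shock genes, 16 fell at 1 µg with ELF1 (17), FOXP1, GATA1, IRF4 and SOX2 (16 each). With FOXO1, FOXP3 and SP4 15 fell (15 each). Values in parentheses are adjusted over the list alone. KLF1 and TCF3 had 14 that fell (14 and 15), KLF4 and OCT4 12 (13 and 12), and ALX4 and LEF1 11 (15 and 13). IKZF2 had 8 (9), MYC and SPI1 7 (7 each), and BACH2 and NR4A1 6 (9 and 10). MXD1 had 3 (11), PRDM1 2 (2) and XBP1 1 (8). At most 3 rose, with PRDM1. The largest median log2 change was -0.98 with TCF3 and the smallest fall -0.13 with MYC and SPI1, and PRDM1 had a median of 0.06. The list passed with an estimated correlation for FOXP1 (adjusted p = 0.000137), ALX4 (0.000169), FOXO1 (0.00115) and ELF1 (0.0191). It did not for SP4 (0.0637) or BACH2 (0.399). For MYC, PRDM1 and SPI1 it did not pass camera (adjusted p = 0.167, 0.556 and 0.144).

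**Figure D4:**
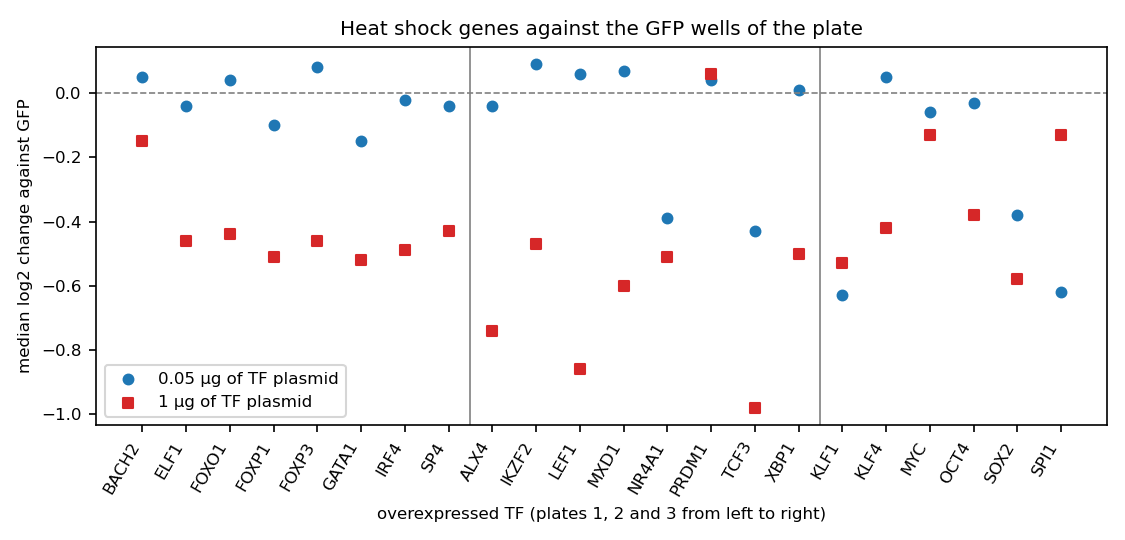
Median log2 change of 20 tested heat shock genes against the GFP wells of the plate, for each TF at 0.05 and 1 µg of TF plasmid. At 1 µg all TFs but PRDM1 lie below 0, down to -0.98 for TCF3.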

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

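The tests of the GFP plasmid share for heat shock genes and of the length bias of a GFP library were chosen only after the result was seen, as were the fits with GC content offsets. In groups of 4 wells, a well is picked out here when its gap to the nearest other, over the range, exceeds Dixon's 95% critical value, and chance picks about 1 in 20 of the 18 groups tested. The KLF1 transcript at 0.25 µg was 9290 CPM in replicate 4 and 37000 to 40800 CPM in the others. The KLF1 relative response at 0.25 µg was 0.614 in replicate 4 and 0.99 to 1.003 in the others. The SPI1 transcript at 1 µg was 140000 CPM in replicate 1 and 105000 to 110000 CPM in the others.

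The relative response at 0.25 µg differed between TFs (permutation p = 1e-05, GFP error left out). On plate 1 all TFs of columns 2 to 6 (0.617 to 0.894) lay above those of columns 7 to 11 (0.398 to 0.555). This part of the difference cannot be told apart from position. Of tested genes, 5.95% differed between KLF4 and KLF1, 0.827% between FOXP1 and FOXO1 and 1.13% between FOXP3 and FOXP1. Targets without a gene name held 13.5% of the counts with MYC at 1 µg and 1.2% with FOXP3, against at most 0.95% in GFP wells. The added XBP1 sequence reached 528 CPM in 1 well without XBP1 plasmid, IKZF2 at 0.05 µg replicate 1, which lies beside a well with 1 µg of XBP1 plasmid, and was at 0 in the GFP wells. Of 100 assignments of KLF1 libraries to doses, the real one gave the most trend genes (9.6% of tested genes, against at most 5.47% in others). For SPI1 it did too (9.42%, against at most 0.98%). This excludes neither position nor chance for single genes.

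At 0.05 µg, ELF1, FOXP1, GATA1 and SP4, in columns 2 to 6 of plate 1, had 36 to 84 falling and at least 138 rising genes, while the TFs in columns 7 to 11 had at most 3 in all. The genes called for 1 of these TFs moved with the others of these columns by a share of their change that was 0.43 higher than with TFs of columns 7 to 11, which is consistent with an effect of position. NEUROD2 and GOLM2, chosen after their values were seen, had medians of 9.01 and 151 CPM in columns 2 to 6 against 0.688 and 48 CPM in columns 7 to 11, and GOLM2 was also at 273 CPM in GFP replicate 1 of plate 2 and at 280 and 424 CPM in the GFP wells of plate 3. With GC content offsets the mean count fell from 219.5 to 77.5, between the bounds set for a trend in GC content, so how much of the pattern such a trend carries stays open. TFs are tied to their position, so a shared effect of these TFs cannot be told apart from it.

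Heat shock genes were lower at higher TF dose on plates 1 and 2. Columns 6 and 7, side by side with 0.05 and 1 µg, differed by a median log2 of -0.38. This argues against a gradient over columns, though their TFs differ. The matching value for 1 against 0.05 µg over the plate (-0.38) shares these wells. Slopes per µg on the left and right of the plate (-0.44 and -0.49) argue against distance from the edge. The 1 µg wells lie near it in column 2 and far from it in column 7. Wells with 0.05 µg lay at a median of 0 from the GFP wells against -0.49 at 1 µg (spread 0.05), as a falling share of GFP plasmid would give, and on plate 3 at -0.22 against -0.4 (spread 0.16), which decides nothing. NR4A1 and TCF3, however, were at -0.39 and -0.43 already at 0.05 µg, and PRDM1 and NR4A1 had slopes of 0 and -0.11, which a share that was the same for every TF would not give by itself. The plasmid share and a response to TF dose itself stay open, since TF and GFP plasmid always changed together.

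Cytoplasmic ribosomal protein genes were lower than in the GFP wells on plate 2, by a median over the 8 TFs of -1.48. Without GFP replicate 1, whose counts fell with transcript length, the median was -0.13 (spread 0.24), as a length bias of that library would give. The dose slopes, which use no GFP library, had a median of 0.21 per µg (spread 0.24), which argues against a fall with dose common to the 8 TFs. Slopes ran from -0.9 with TCF3, -0.5 with LEF1 and -0.29 with ALX4 to 0.77 with IKZF2. Counts also fell with transcript length in the other libraries of plate 2 that stood apart (slopes of -0.385 to -1.11). This may have moved the dose slopes of TCF3, IKZF2, PRDM1 and XBP1 and the median. A fall with the dose of single TFs stays open.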

How the results depend on the processing

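DESeq2 size factors left every count of changed genes within 1.5 times, and every named gene called. Of 262 results of genes taken by the naming rule 17 lost their call with only the wells of the TF and GFP in the fit, HSPA5 with XBP1 lost it also with no filter, with transcript length offsets and without any 1 replicate, and CA2 with GATA1 with pooled GFP libraries. Replicate numbers do not pair the wells: deviations of wells with the same number correlated at a median of -0.002, -0.026 and 0 on plates 1 to 3 (from -0.886 to 0.943). With the replicate block no count moved by over 1.5 times (6.52% of tested genes between KLF4 and KLF1 against 5.95%), and 2 list results lost their call. Fits without 1 library reuse the scaling, tested genes and trended spread of all libraries, and a lone well is assumed to vary like the other groups. The slope threshold over the logarithm of the dose was scaled to the same change over the dose range. Fits without the 8 libraries that stood apart and with GC content offsets were chosen after seeing the data. Scaling moved the median log2 change of all genes by over 0.1 only with GC content offsets (by 0.171 for KLF4, 0.14 for KLF1, 0.105 for SPI1 and 0.103 for SP4, and 0.148 for the TCF3 slope) and, for the TCF3 slope, with DESeq2 size factors (0.11). For all changes given here the cause was not tested.

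Counts are given here as percent of the genes tested on the plate. Genes changed at 1 µg were IKZF2 2.48%, MXD1 0.226%, NR4A1 0.617%, XBP1 0.259%, MYC 4.94%, BACH2 2.47%, FOXP1 1.47%, FOXP3 4.36%, GATA1 1.59%, IRF4 5.17%, LEF1 3.47%, TCF3 9.9%, ALX4 6.78% and PRDM1 9.4%. With pooled GFP libraries they were IKZF2 6.3, MXD1 0.589, NR4A1 1.19, XBP1 0.837 and MYC 7.99, and with DESeq2 MXD1 1.1, NR4A1 1.06 and XBP1 1.05. With GC content offsets they were BACH2 1.45, FOXP1 0.892, FOXP3 2.52, GATA1 0.963, IRF4 2.84 and MXD1 0.584. With only TF and GFP wells they were GATA1 0.903, IKZF2 0.303, MXD1 0.022, NR4A1 0.281, PRDM1 0.0386, TCF3 2.01 and XBP1 0 (edgeR; 190 genes by DESeq2 with all wells). With no filter they were LEF1 6.46, MXD1 4.05, NR4A1 3.46 and XBP1 3.94, and without the libraries that stood apart MXD1 0.766, NR4A1 1.26 and XBP1 1.09. Without 1 replicate they ranged for FOXP1 from 0.908 to 1.4, GATA1 0.968 to 1.77, ALX4 1.96 to 18.5, IKZF2 1.33 to 4.99, LEF1 1.01 to 15.9, MXD1 0.022 to 13.5, NR4A1 0.138 to 12, PRDM1 8.89 to 16.1, TCF3 4.41 to 20.7 and XBP1 0.0496 to 12.2.

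Genes with a dose trend, in the same percent, were ELF1 7.17, FOXO1 3.44, FOXP1 0.223, FOXP3 3.7, GATA1 0.49, IRF4 4.63, ALX4 4.55, IKZF2 3.44, LEF1 1.16, MXD1 0.32, NR4A1 0.0606, PRDM1 8.44, TCF3 10.5, XBP1 0.584, KLF4 9.83, MYC 3.07, OCT4 8.61 and SOX2 14. They were NR4A1 0.116 with DESeq2 and FOXP3 2.13 with GC content offsets. With only TF and GFP wells they were GATA1 0.109, IKZF2 0.303, NR4A1 0.022, PRDM1 0.0441, TCF3 0.308 and XBP1 0.00551. With no filter they were FOXP1 0.74, GATA1 0.854, IKZF2 5.65, MXD1 0.744, NR4A1 0.358 and XBP1 1.36. Over the logarithm of the dose they were FOXO1 2.01, LEF1 1.78, NR4A1 0.127 and XBP1 0.375, and with transcript length offsets GATA1 0.305 and NR4A1 0.0386. Without the libraries that stood apart they were ALX4 7.6, LEF1 2.55, MXD1 1.5, NR4A1 0.667, TCF3 5.35 and XBP1 1.6. Without 1 replicate they ranged for ELF1 from 4.39 to 5.76, FOXO1 2.14 to 2.42, FOXP1 0.049 to 0.245, FOXP3 1.68 to 2.72, GATA1 0.19 to 0.31, IRF4 2.88 to 3.56, ALX4 0.7 to 1.69, IKZF2 0.413 to 5.08, LEF1 0.143 to 0.182, MXD1 0.0386 to 0.0826, NR4A1 0.00551 to 0.011, PRDM1 4.42 to 16.5, TCF3 1.68 to 31.6, XBP1 0.0441 to 0.198, KLF4 6.55 to 7.63, MYC 1.51 to 1.97, OCT4 4.32 to 9.71 and SOX2 9.28 to 13.5. Between FOXP1 and FOXO1 1.42% of tested genes differed with no filter, 0.533% with transcript length offsets and 0.451 to 0.843% without 1 replicate (0.827% in the fit of all wells), and between FOXP3 and FOXP1 0.702% with transcript length offsets and 0.593 to 0.713% without 1 replicate (1.13%). Fitted rises of the added sequences, over 0 counts in the GFP wells and so no measure of size, were 21 log2 units for FOXO1 (adjusted p = 0.22) and 36.82 for XBP1 (adjusted p = 0.0977) with DESeq2, and 23.59 to 23.87 for XBP1 without 1 replicate, where the call was lost without GFP replicate 1 (adjusted p = 0.0773).

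The relative response with pooled GFP libraries was BACH2 0.638, ELF1 0.627, FOXO1 0.772, FOXP1 0.838, FOXP3 0.643, IRF4 0.565, SP4 0.656, ALX4 0.631, IKZF2 0.641, MXD1 1.496, PRDM1 0.607, MYC 0.893, OCT4 0.625, SOX2 0.589 and SPI1 0.895. With DESeq2 size factors it was ELF1 0.614, SP4 0.633, IKZF2 0.857, MYC 0.831 and SOX2 0.522. Over genes with a mean change of at least 0.5 it was ELF1 0.719, FOXP1 0.904, GATA1 1.148, SP4 0.751, ALX4 0.759, IKZF2 0.885, LEF1 0.717, MXD1 1.655, NR4A1 1.79, PRDM1 0.829, KLF4 0.903, MYC 0.755, OCT4 0.653, SOX2 0.552 and SPI1 0.836. Over dose trend genes it was BACH2 0.092, ELF1 0.419, FOXO1 0.199, FOXP1 0.344, FOXP3 0.234, GATA1 0.347, IRF4 0.283, SP4 0.417, ALX4 0.438, IKZF2 0.44, LEF1 0.49, MXD1 1.591, PRDM1 0.337, TCF3 0.596, KLF1 0.598, KLF4 0.505, MYC 0.327, OCT4 0.311, SOX2 0.364 and SPI1 0.467. Without the libraries that stood apart it was ALX4 0.65, IKZF2 0.642, LEF1 0.75, PRDM1 0.581 and SOX2 0.534. Without 1 replicate it ranged for BACH2 from 0.418 to 0.516, ELF1 0.603 to 0.643, FOXP1 0.733 to 0.857, FOXP3 0.434 to 0.5, GATA1 0.829 to 1.318, IRF4 0.479 to 0.58, SP4 0.65 to 0.673, ALX4 0.6 to 0.923, IKZF2 0.501 to 1.432, LEF1 0.677 to 0.942, MXD1 1.216 to 1.666, NR4A1 1.221 to 1.811, PRDM1 0.525 to 1.145, TCF3 0.843 to 1.709, MYC 0.805 to 0.868, OCT4 0.574 to 0.597, SOX2 0.505 to 0.545 and SPI1 0.747 to 0.816.

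With an estimated correlation 148 list results lost their call, among paired lists NRF2 targets of BACH2 (adjusted p = 0.3), FOXO targets of FOXO1 (0.177), T cell genes of IKZF2 (0.179), MHC class I genes of IRF4 (0.326), MYC targets of MXD1 (0.18) and MYC (0.35), G1/S genes of MYC (0.646), immediate early genes of NR4A1 (0.153), myeloid and B cell genes of SPI1 (0.129 and 0.0562) and ER genes of XBP1 (0.0518). With fry, which does not compare a list with other genes, 25 list results lost their call, 0 of them paired, and T cell genes of ELF1 (4.4e-06) and FOXP3 (0.00992), pluripotency genes of KLF4 (5.2e-15), Wnt targets of LEF1 (0.0434), germline genes of OCT4 (0.00511), neural genes of SOX2 (0.00853), cholesterol genes of SP4 (2.4e-05) and muscle genes of TCF3 (0.00314) passed. Without the libraries that stood apart 12 list results lost their call, among paired lists T cell genes of IKZF2 (adjusted p = 0.473), while pluripotency genes of KLF4 passed (adjusted p = 0.0485) and ribosomal protein genes of NR4A1 turned to higher (adjusted p = 5.28e-06). Over all tested genes the correlation of slopes was 0.468 for KLF1 and KLF4, 0.474 for OCT4 and SOX2, 0.349 for KLF4 and SP4, 0.291 for FOXO1 and FOXP3, 0.277 for ELF1 and SPI1, 0.231 for KLF1 and SP4 and -0.044 for GATA1 and KLF1. From single replicates it was 0.363 for KLF1 and KLF4, 0.343 for OCT4 and SOX2, 0.181 for LEF1 and SOX2, 0.071 for FOXP1 and FOXP3, 0.058 for FOXO1 and FOXP1, and reversed to -0.01 for KLF1 and SP4.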

Other observations

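A hypothesis was that TFs with a high relative response at 0.25 µg may have a TF transcript already near its plateau at that dose. Over 21 TFs the relative response rose with the ratio of the TF transcript at 0.25 µg to that at 1 µg (r = 0.802, permutation p = 0.00014; rho = 0.442). Without NR4A1 and MXD1, the TFs farthest from the median, r was 0.388 (permutation p = 0.0982), so the relation rests on them, and within plates r was 0.433, 0.899 and -0.015. The hypothesis stays open.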
